A study of Mus musculus with 20 samples.

How the data were processed

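RNA from the livers of mice labelled as OGT liver knockout (KO) or wild type (WT), aged 4 or 8 weeks, was measured on 20 Clariom S Mouse arrays, 5 per group. OGT is the O-GlcNAc transferase, the enzyme that attaches N-acetylglucosamine to serine and threonine residues of intracellular proteins. Groups were taken from the genotype and age labels of each sample, and the series text states 5 mice per group. The array number in the sample titles runs in the order of the groups, so array order and group could not be separated, and scan dates and batches were not used here.

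The authors processed the arrays in Affymetrix Expression Console with RMA, per the submitters' processing notes, and the versions were not given in the sources used here. The deposited values were log2 signals and were used without further scaling. They ran from 2.32 to 19.85, and 254 to 288 features per array lay above 16, the log2 ceiling of a 16-bit scanner. The sources used here did not say how values above that ceiling arose, so fold differences are stated on the deposited scale and may be stretched. Array medians ran from 5.42 to 5.58. Correlations of single arrays with the others of their group ran from 0.974 to 0.993, and no 2 arrays were identical. Detection p-values and the raw image files were not used here. A background level was set after the results were seen, from 1410 olfactory and vomeronasal receptor genes, taken as not expressed in liver. It was the 95th percentile of their group means, which was 5.02 in WT and 5.04 in KO at 4 weeks and 5.20 in WT and 5.02 in KO at 8 weeks. A group mean at or below it, as for 41.7% to 45.4% of genes, is called not above background, and a difference against such a group is a lower limit, stated as "at least" with the level in place of the mean.

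The table held 22206 features. A single gene symbol was given for 19572 of them, and 2634 unnamed features were left out of the gene tests. For the 55 symbols with more than 1 feature the feature with the highest mean over all arrays was kept, which removed 67 features and left 19505 genes. Features of near-identical paralogs, such as the Mup, Cyp4a12, Gstp, Sult2a and Ifit3 genes, cannot be assigned to 1 gene with certainty, and the symbol in the array annotation was used.

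Linear models with 4 group means were fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and 16 residual degrees of freedom. The comparisons were KO against WT at 4 weeks, KO against WT at 8 weeks, the KO effect at 8 weeks minus that at 4 weeks (interaction), and 8 weeks against 4 weeks within WT and within KO. P-values were adjusted by the Benjamini-Hochberg method over the 19505 genes, and a gene was called higher or lower at an adjusted p below 0.05. Differences are log2 differences of group means, and a 2-fold difference is 1 log2 unit. Exact permutation p-values for 5 against 5 arrays cannot be smaller than 0.00794. Groups of 5 arrays each without overlap arise by chance for 0.794% of genes. The number of arrays limits the precision of all values.

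Before the data were examined, 38 gene lists with 905 different genes were written down. They covered hexosamine and O-GlcNAc cycling, carbohydrate, lipid, bile acid, xenobiotic, amino acid and iron metabolism, hepatocyte identity and zonation, fetal genes, cell types of the liver, inflammation, interferon, stress responses, cell cycle, cell death, sex-biased genes, the Y chromosome, the clock, growth hormone, mitochondria and lysosomes. Of the listed genes 824 were measured, and the others were not analysed here. Lists were tested with camera at the preset inter-gene correlation of 0.01, with adjustment over the 38 lists in each comparison. The median and mean difference of the members are descriptive. Member counts used the genome-wide adjusted p, and a second count, called adjusted over the list alone, adjusted the p-values within the list.

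Genes were named by a rule fixed before the data were examined. For KO against WT at each age these were Ogt, the 8 largest rises and 8 largest falls among called genes whose groups did not overlap, and up to 4 members with the smallest adjusted p of each list described. For the interaction and the age comparisons, 5 genes in each direction and up to 3 members per list were named, and the interaction had no overlap condition. Symbols of the Gm-number and Rik kinds were to be passed over, and 0 were met.

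The script was tested on simulated data with changes added to 100 genes each of log2 size 1 and 2 among 19505, and of size 0.5 to a list of 25 others. At 4 weeks 81% and 99% were recovered with 8 false calls among 193, and at 8 weeks 88% and 100% with 14 false calls among 204. The totals include 5 and 2 genes of the list of 25. The simulated noise was normal, with the moderated SD of each gene, and independent between genes and arrays. No age effect and no muscle transcripts were put in, so these rates hold for that setting and not for the real arrays.

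Alternatives were repeated quantile normalization, array medians set equal, the dimmest 25% of genes left out, all 22206 features tested, the mean of all features of a gene, a variance trend with a robust prior, only the 2 compared groups in the fit, array weights, a replicate block, each array left out in turn, and camera with an estimated correlation or with ranks. The replicate block adds a term for the replicate number to the fit. One alternative, a fit without 3 arrays that held skeletal muscle transcripts, was added after the values were seen.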

Results

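Liver transcripts were compared between mice labelled as OGT liver knockout (KO) and wild type (WT) at 4 and 8 weeks of age. Each of the 4 groups had 5 arrays, and 19505 genes were tested on the deposited log2 scale. Values below are group means ± SD of log2 signal with n = 5 per group, and differences are in log2 units. Eif2s3y, a gene of the Y chromosome, ran from 11.08 to 12.09 over the 20 arrays. The question was how loss of OGT in the liver alters gene expression at each age, and whether the effect differs between the ages.

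Ogt itself (feature TC0X00000981.mm.2) was 8.14 ± 0.53 in KO and 9.57 ± 0.31 in WT liver at 4 weeks (n = 5 each). The difference of -1.43 (SE 0.20) put KO at 37.1% of WT, with a limma adjusted p of 8.82e-05 and an exact permutation p of 0.00794. Single arrays ran from 7.37 to 8.84 in KO and from 9.14 to 9.87 in WT. At 8 weeks the arrays labelled KO had an Ogt signal of 9.81 ± 0.21, and WT had 10.08 ± 0.20. That difference was -0.27, or 83.2% of WT, with an adjusted p of 0.529 and an exact p of 0.0794, and the groups overlapped (9.55 to 10.01 against 9.84 to 10.33). The Ogt difference at 8 weeks minus that at 4 weeks was 1.16 (SE 0.29, limma adjusted p = 0.0307). This call was lost on leaving out any of 7 arrays, with adjusted p from 0.0514 to 0.0605. Which exons the feature covers was not given in the sources used here, so the signal is not a measure of intact transcript. The results at 8 weeks describe arrays labelled KO, whose Ogt signal was not called different from WT.

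**Figure D1:**
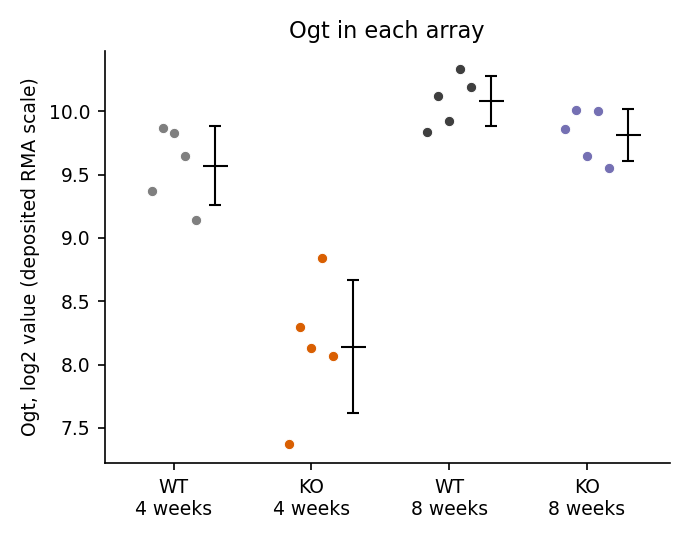
Log2 signal of Ogt in each of the 20 arrays by group, with points for arrays and bars for mean ± SD (n = 5). Group means were 9.57 and 8.14 in WT and KO at 4 weeks, and 10.08 and 9.81 at 8 weeks.

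The macrophage metalloelastase gene Mmp12 rose most at 4 weeks, from 4.86 ± 0.43 in WT to 10.98 ± 0.96 in KO (difference 6.12, adjusted p = 3.60e-07). Elovl3, which encodes a fatty acid elongase, rose from 5.47 ± 1.90 to 10.85 ± 1.55 (5.38, adjusted p = 1.19e-04). The glutathione transferase gene Gsta2 rose from 11.77 ± 0.87 to 15.97 ± 0.25 (4.20, adjusted p = 3.54e-07), and the collagenase gene Mmp13 from 3.84 ± 0.35 to 7.80 ± 0.36 (3.96, adjusted p = 1.96e-07). In WT Mmp12 and Mmp13 were not above background, so these rises were at least 5.96 and 2.78. Irf7, a transcription factor of the interferon response, rose from 8.18 ± 0.75 to 12.18 ± 0.91 (4.00, adjusted p = 1.92e-06). The features annotated to Mup20 (4.26) and Ifit3b (3.92) also rose, although paralogs of near-identical sequence leave their assignment uncertain. The largest fall was that of Hao2, a hydroxyacid oxidase gene with female-biased expression, from 12.67 ± 0.53 to 8.79 ± 1.07 (-3.88, adjusted p = 9.24e-07). The transporter gene Slc22a26 (-3.57), the steroid dehydrogenase gene Hsd3b1 (-3.26) and the sulfotransferase gene Sult3a1 (-3.03) fell. So did the acute phase gene Orm1 (-2.84), the P450 gene Cyp2c69 (-2.80), Ugt3a1 (-2.78) and the carboxylesterase gene Ces1f (-2.70). In all, 917 genes were higher and 1068 lower in KO at 4 weeks, which is 10.2% of those tested. Of these, 312 were higher and 319 lower by at least 2-fold. The groups did not overlap for 1667 genes (8.55%), against 0.794% by chance.

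Interferon-stimulated genes were higher in KO liver at 4 weeks. Ifit1, an antiviral effector gene, rose from 6.90 ± 0.37 to 11.05 ± 0.81 (4.15, adjusted p = 1.11e-06), and Rsad2, which encodes viperin, from 8.38 ± 0.28 to 12.13 ± 0.94 (3.74, adjusted p = 1.24e-06). Of 28 measured genes of this list 24 were higher, 0 lower and 4 neither (26 higher adjusted over the list alone). The median difference was 1.76 (adjusted p = 2.87e-32 by camera). Targets of the oxidative stress regulator NRF2 rose as well, among them Gstm3 (3.05), Gsta2 and the sulfiredoxin gene Srxn1, from 7.11 ± 0.58 to 10.82 ± 1.17 (3.71, adjusted p = 4.87e-06). The count was 20 higher, 2 lower and 12 neither of 34 (22 and 3 adjusted over the list alone), with a median of 0.71 and an adjusted p of 1.12e-14. Macrophage genes, which covered monocyte-derived and lipid-associated macrophages, included Cd63 (3.02), Cd9 (2.03) and Gpnmb (1.63, from 4.30 ± 0.19, not above background, to 5.93 ± 0.25, so at least 0.91). Of 25 genes 10 were higher, 1 lower and 14 neither (16 and 1 adjusted over the list alone), with a median of 0.56 and an adjusted p of 1.94e-10. Chemokines rose, with Cxcl9, which attracts T cells, going from 10.14 ± 1.22 to 13.84 ± 0.91 (3.70, adjusted p = 2.06e-04). Cxcl10 (3.85), the pattern recognition receptor gene Tlr2 (2.12) and the adhesion molecule gene Icam1 (0.84) were also higher. The chemokine and cytokine list had 12 higher, 1 lower and 21 neither of 34 (14 and 1 adjusted over the list alone), with a median of 0.41 and an adjusted p of 7.12e-07.

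Genes of cell death rose at 4 weeks, with the TWEAK receptor gene Tnfrsf12a rising by 2.48 (adjusted p = 2.10e-05) and the necroptosis effector gene Mlkl from 9.19 ± 0.79 to 11.12 ± 0.28 (1.92). Of 23 genes 6 were higher, 0 lower and 17 neither (8 higher adjusted over the list alone). The median was 0.33 with an adjusted p of 2.07e-06, and adjusted p = 0.0879 with an estimated correlation. Alpha-fetoprotein (Afp) rose from 6.55 ± 0.18 to 9.09 ± 0.77 (2.54, adjusted p = 1.59e-05), and Anxa5 rose by 1.88, while the imprinted gene Mest fell by 1.26. Fetal and regenerating hepatocyte genes counted 6 higher, 1 lower and 13 neither of 20 (7 and 1 adjusted over the list alone). Their median was 0.62 with an adjusted p of 0.00219, and adjusted p = 0.226 with an estimated correlation. The keratin genes Krt18 (2.10) and Krt8 (1.76), which are expressed in hepatocytes as well as in bile ducts, and Wfdc2 (1.19) led the cholangiocyte and ductular list. It had 4 higher, 0 lower and 18 neither of 22 (8 higher adjusted over the list alone), with a median of 0.42 and an adjusted p of 7.96e-05, and adjusted p = 0.307 with an estimated correlation. In the stellate cell, myofibroblast and collagen list Mmp13 and Mmp12 rose and the fibronectin gene Fn1 fell from 16.72 ± 0.12 to 16.01 ± 0.14 (-0.72, adjusted p = 3.94e-04). Mmp12 is also on the macrophage list. Timp1 (0.57) was called higher too but was not above background in either group, and no collagen gene was called. Of 37 genes 3 were higher, 1 lower and 33 neither (3 and 1 adjusted over the list alone). The median of 0.33 had an adjusted p of 0.00665, and adjusted p = 0.508 with an estimated correlation. The call was also lost without KO_4w replicate 4 (adjusted p = 0.112) and without the 3 arrays described next (adjusted p = 0.0826). Among T and NK cell genes, Cd3e (0.78) and the kinase gene Zap70 (-0.60) were called, but they were not above background in either group. This list had 3 higher, 1 lower and 18 neither of 22 (5 and 1 adjusted over the list alone). The median of 0.22 had an adjusted p of 0.00698, and adjusted p = 0.226 with an estimated correlation.

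Skeletal muscle transcripts were high in 3 of the 10 arrays at 4 weeks. Acta1, the skeletal actin gene, was 15.89 in WT_4w replicate 4, 15.04 in KO_4w replicate 4 and 15.43 in KO_4w replicate 5, and 4.24 to 6.11 in the other 17 arrays. Both genotypes held such an array. These 3 arrays were kept in the values above. In WT_4w replicate 3 the muscle genes used to find them had a mean of 6.03, against 4.67 to 5.12 in the remaining arrays at 4 weeks. Muscle genes not used for that had a mean of 4.46 in it, so a trace there is not excluded. Des (0.70, adjusted p = 0.830) and Acta2 (0.26, adjusted p = 0.859), which muscle also expresses, are members of the stellate list.

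Sterol genes fell at 4 weeks. Stard4, which encodes a cholesterol transfer protein, fell from 12.03 ± 0.26 to 10.05 ± 0.47 (-1.98, adjusted p = 1.92e-06), the sterol oxidase gene Msmo1 by 1.49 and Hsd17b7 by 1.71. Of 19 genes of cholesterol synthesis and uptake 0 were higher, 10 lower and 9 neither (15 lower adjusted over the list alone). The median was -0.86 with an adjusted p of 2.11e-10, and adjusted p = 0.139 with an estimated correlation. The desaturase gene Fads1 fell by 0.81 and Acss2, which makes acetyl-CoA from acetate, by 1.59. De novo lipogenesis counted 0 higher, 3 lower and 16 neither of 19 (3 lower adjusted over the list alone). Its median of -0.37 had an adjusted p of 0.00730, and adjusted p = 0.379 with an estimated correlation. Fgf21, a hormone gene induced by fasting and by stress, rose from 4.25 ± 0.16, not above background, to 6.45 ± 1.12 (2.20, at least 1.44, adjusted p = 3.48e-04), while the thioesterase genes Acot3 (-2.26) and Acot1 (-1.52) fell. Acot3 is also on the female-biased list. Fatty acid oxidation and PPARalpha targets had 1 higher, 7 lower and 19 neither of 27 (1 and 9 adjusted over the list alone). The median of -0.38 had an adjusted p of 0.0137, and adjusted p = 0.388 with an estimated correlation. That call was lost without KO_4w replicate 2 (adjusted p = 0.0939) and with quantile normalization repeated (adjusted p = 0.0643). Foxo1, a regulator of gluconeogenesis, fell from 10.77 ± 0.20 to 9.49 ± 0.42 (-1.28) and the insulin receptor substrate gene Irs2 by 1.03. Gluconeogenesis and glycogen counted 0 higher, 2 lower and 13 neither of 15 (6 lower adjusted over the list alone). The median was -0.53 with an adjusted p of 0.00368, and adjusted p = 0.154 with an estimated correlation.

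Fgfr4, the receptor through which FGF15 represses bile acid synthesis, fell from 7.43 ± 0.34 to 5.33 ± 0.55 at 4 weeks (-2.10, adjusted p = 2.78e-05). The bile acid genes Slc27a5 (-0.85) and Cyp27a1 (-0.89) fell too. Bile acid synthesis and transport had 1 higher, 6 lower and 20 neither of 27 (1 and 12 adjusted over the list alone). The median of -0.53 had an adjusted p of 5.99e-04, and adjusted p = 0.178 with an estimated correlation. Nr1i3, which encodes the xenobiotic receptor CAR, fell by 1.47 and Cyp2f2 by 1.08 (16.95 ± 0.44 to 15.87 ± 0.44). Xenobiotic P450 enzymes counted 1 higher, 7 lower and 14 neither of 22 (3 and 9 adjusted over the list alone). Their median of -0.50 had an adjusted p of 0.00426, and adjusted p = 0.275 with an estimated correlation. The aminotransferase genes Kyat1 (-1.91, adjusted p = 4.01e-05) and Gpt (-1.09) and the tyrosine catabolism gene Fah (-0.66) fell. Of 25 genes of the urea cycle and amino acid catabolism 0 were higher, 6 lower and 19 neither (8 lower adjusted over the list alone). The median was -0.52 with an adjusted p of 1.80e-07, and adjusted p = 0.226 with an estimated correlation. The coagulation factor gene F11 fell from 12.53 ± 0.26 to 10.90 ± 0.38 (-1.63, adjusted p = 2.70e-06) and Itih1 by 1.17. Hepatocyte identity and plasma proteins had 0 higher, 4 lower and 29 neither of 33 (5 lower adjusted over the list alone), with a median of -0.28 and an adjusted p of 3.05e-06. Genes of both hepatocyte zones fell, with Rgn (-0.84) pericentral and Sfxn1 (-1.09) periportal, while Hsd17b13 rose by 0.97. The pericentral list counted 2 higher, 6 lower and 15 neither of 23 (2 and 9 adjusted over the list alone), with a median of -0.33 and an adjusted p of 0.00812, and adjusted p = 0.241 with an estimated correlation. The periportal list counted 1 higher, 5 lower and 16 neither of 22 (2 and 7 adjusted over the list alone). Its median of -0.48 had an adjusted p of 0.00426, and adjusted p = 0.307 with an estimated correlation. Stab2, a scavenger receptor gene of sinusoidal endothelium, fell from 8.22 ± 0.21 to 7.16 ± 0.21 (-1.07). Sinusoidal endothelium had 0 higher, 2 lower and 19 neither of 21 (2 lower adjusted over the list alone). The median of -0.24 had an adjusted p of 0.00454, and adjusted p = 0.388 with an estimated correlation.

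Female-biased liver genes fell at 4 weeks, with Hao2, Cyp2c69 and Slc22a26 as above and Acot4 from 7.17 ± 0.39 to 5.59 ± 0.56 (-1.58). Of 31 genes 0 were higher, 10 lower and 21 neither (1 higher and 13 lower adjusted over the list alone), with a median of -0.98 and an adjusted p of 1.02e-07. Among male-biased genes Elovl3 and Cyp2u1 (1.63, adjusted p = 7.75e-04) rose. That list had 5 higher, 3 lower and 18 neither of 26, with a median of 0.18 and an adjusted p of 0.0904. Igfals, which encodes the acid-labile subunit of the IGF complex, fell from 10.90 ± 0.67 to 8.91 ± 0.43 (-1.99, adjusted p = 2.44e-04), and the growth hormone receptor gene Ghr fell by 0.66. The growth hormone and IGF list had 0 higher, 4 lower and 12 neither of 16 (4 lower adjusted over the list alone), with a median of -0.37 and an adjusted p of 0.00523. None of the 3 measured genes of the Y chromosome was called alone at 4 weeks (3 lower adjusted over the list alone). Their median was -0.45 with an adjusted p of 0.0306, and adjusted p = 0.178 with an estimated correlation. That call was lost without WT_4w replicate 3 (adjusted p = 0.0584) or KO_4w replicate 5 (adjusted p = 0.0556), and with the dimmest 25% of genes left out (0.0545).

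At 4 weeks 23 of the 38 lists were called by camera with the preset correlation, and 7 of these held with an estimated correlation. The 7 were interferon and NRF2 (adjusted p = 0.01001 each), macrophage (0.0295), chemokine (0.0260), hepatocyte identity (0.0496), female-biased (0.0272) and growth hormone (0.0425). With array medians set equal, 703 genes were higher and 1414 lower, so the share of higher genes was 33.2% in place of 46.2%.

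**Figure D2:**
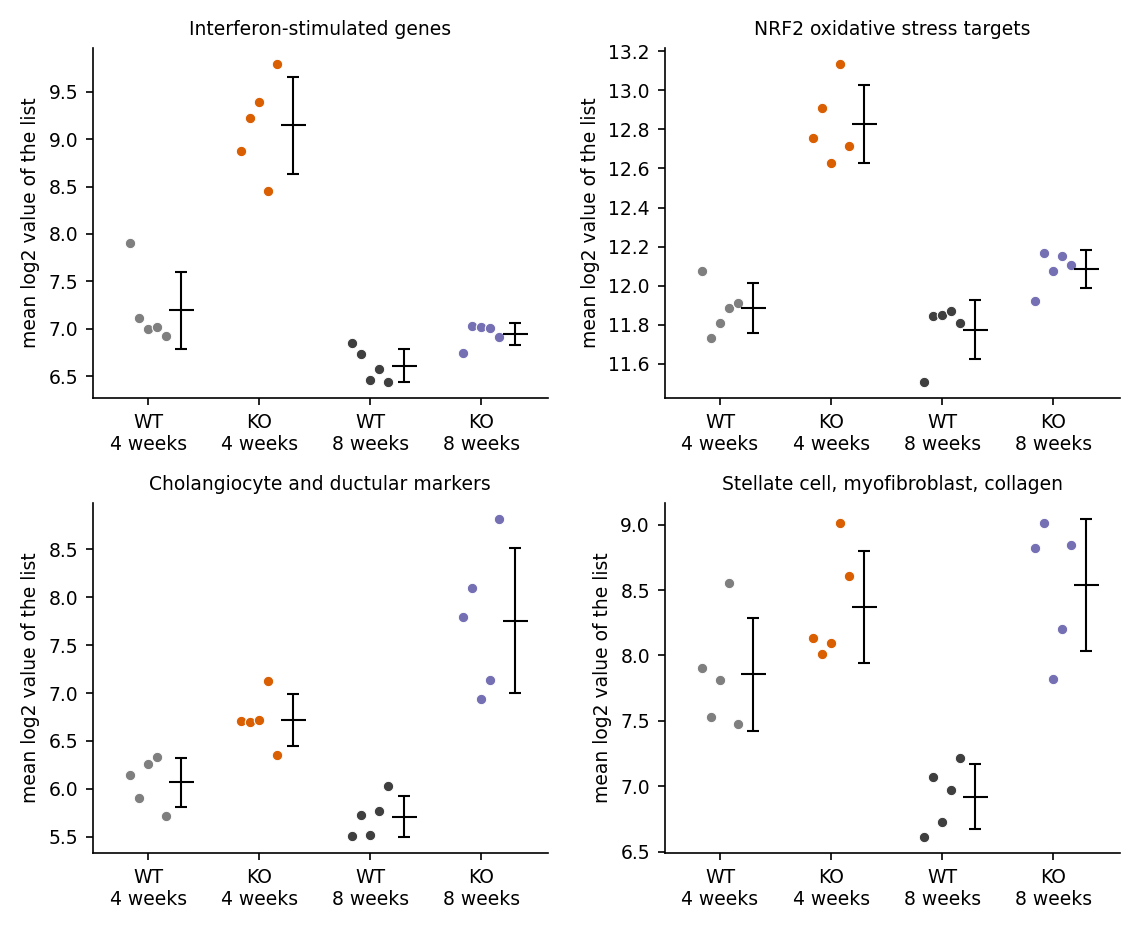
Mean log2 signal of 4 gene lists in each array by group, with points for arrays and bars for mean ± SD (n = 5). The interferon mean was 7.19, 9.15, 6.61 and 6.94 and the stellate mean 7.85, 8.37, 6.92 and 8.54 in WT and KO at 4 weeks and WT and KO at 8 weeks.

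At 8 weeks the tetraspanin gene Tspan8, which marks bile duct epithelium, rose most, from 5.27 ± 0.75 in WT to 11.04 ± 1.45 in the arrays labelled KO (5.77, adjusted p = 1.16e-05). Ntrk2, which encodes the BDNF receptor, rose from 5.56 ± 0.62 to 10.47 ± 0.36 (4.91, adjusted p = 8.23e-09) and Pdzk1ip1 from 6.18 ± 0.70 to 11.15 ± 1.08 (4.97, adjusted p = 4.52e-07). The matrix gene Sparcl1 (5.06), Mmp12 (4.64), Fam180a (4.29), the epithelial adhesion gene Epcam (4.00) and the collagen-binding gene Lum (3.91) rose as well. The complement regulator gene Susd4 fell most, from 10.73 ± 0.51 to 6.88 ± 0.75 (-3.85, adjusted p = 1.71e-07), and the oxysterol hydroxylase gene Cyp7b1 fell from 16.84 ± 0.62 to 14.09 ± 0.84 (-2.75, adjusted p = 8.08e-05). The anion transporter gene Slc22a7 (-2.67), Selenbp2 (-2.67), Phlda1 (-2.61) and the pseudogene Adh6-ps1 (-2.31) fell, as did Capn8 (-2.18) and Sdr9c7 (-2.11). Mmp12 and Epcam in WT and Capn8 in KO were not above background, so their differences were at least 4.29, 3.81 and 0.63 in size. In all, 963 genes were higher and 321 lower, which is 6.58% of those tested, and 543 and 53 of these differed by at least 2-fold. The groups did not overlap for 1189 genes (6.10%), against 0.794% by chance. With array medians set equal the counts were 801 and 856, so the share of higher genes was 48.3% in place of 75.0%, and 98 genes were lower by at least 2-fold in place of 53. The 321 lower genes became 199 without KO_8w replicate 5, 203 without WT_8w replicate 3 and 207 without KO_8w replicate 2.

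Ductular genes were higher at 8 weeks. Bicc1 rose from 7.19 ± 0.27 to 11.03 ± 1.13 (3.85, adjusted p = 1.62e-06) and the cholangiocyte gene Pkhd1, mutated in polycystic disease, from 5.14 ± 0.28 to 8.96 ± 1.09 (3.83, at least 3.77 above background, adjusted p = 2.72e-06). Of 22 genes 17 were higher, 0 lower and 5 neither (20 higher adjusted over the list alone), with a median of 1.76 and an adjusted p of 3.10e-27. Genes of stellate cells, myofibroblasts and collagen rose with Pdgfrb, the PDGF receptor gene of stellate cells, from 6.55 ± 0.36 to 9.28 ± 0.62 (2.74, adjusted p = 1.71e-07). Lum (9.48 ± 0.60 to 13.39 ± 1.11) and the gelatinase gene Mmp2 (3.81) belonged to the same list. It had 25 higher, 0 lower and 12 neither of 37 (29 higher adjusted over the list alone), with a median of 1.30 and an adjusted p of 8.16e-30. Macrophage genes rose with Cd63 from 6.79 ± 0.49 to 10.63 ± 0.81 (3.84), the lysozyme gene Lyz2 (2.39) and the NADPH oxidase gene Cybb (1.80). Their count was 18 higher, 0 lower and 7 neither of 25 (20 higher adjusted over the list alone), with a median of 1.16 and an adjusted p of 3.06e-23. Among chemokines and cytokines Cxcl16 (2.18), the adhesion molecule gene Vcam1 (2.72, from 7.25 ± 0.20 to 9.97 ± 0.75) and the NF-kB target Tnfaip3 (1.45) rose. That list counted 10 higher, 0 lower and 24 neither of 34 (11 and 1 adjusted over the list alone), with a median of 0.24 and an adjusted p of 3.68e-06. Anxa2 (2.73), Cd24a (3.75, from 5.00 ± 0.76 to 8.75 ± 1.48) and the oncofetal gene Gpc3 (2.03) rose among fetal and regenerating hepatocyte genes. In WT Cd24a and Gpc3 were not above background, so they rose by at least 3.55 and 1.21. Afp, which rose at 4 weeks, was 6.42 in WT and 6.65 in KO at 8 weeks. Its KO effect was smaller at 8 weeks than at 4 weeks (interaction -2.31, limma adjusted p = 0.00544), so the 2 ages did not share this rise. Of 20 genes of the fetal list 6 were higher, 0 lower and 14 neither (8 higher adjusted over the list alone). The median was 0.66 with an adjusted p of 1.15e-07, and adjusted p = 0.0516 with an estimated correlation.

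Female-biased genes were higher at 8 weeks, with Rtn4 from 10.65 ± 0.52 to 12.64 ± 0.22 (1.99, adjusted p = 8.16e-06), the transporter gene Slc22a27 (2.29, at least 1.39 above background) and Abcd2 (2.65). Prom1 (3.58) is on this list and is also a marker of ductular cells. Lpl (8.24 in WT and 10.44 in KO) is also on the macrophage list. The ductular and macrophage lists were higher at this age too. Other members did not share the rise. Hao2, Sult2a2 and Sult3a1 were not above background in either group. Sult2a1 was 6.79 in WT and 6.45 in KO, and Cyp2c69 was 11.68 and 12.07. The count for the female-biased list was 9 higher, 0 lower and 22 neither of 31 (9 higher adjusted over the list alone), with a median of 0.56 and an adjusted p of 1.67e-07. Male-biased genes fell with Susd4, Selenbp2 (15.50 ± 0.58 to 12.83 ± 0.50), Cyp7b1 and the peptide transporter gene Slc15a5 (-1.68). Of 26 genes 0 were higher, 7 lower and 19 neither (11 lower adjusted over the list alone). The median was -0.75 with an adjusted p of 5.61e-09, and adjusted p = 0.196 with an estimated correlation.

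Interferon-stimulated genes had 1 of 28 higher, 0 lower and 27 neither at 8 weeks (1 higher adjusted over the list alone). The called gene, Ifi27l2a (0.91), was not above background in either group. The median of 0.20 had an adjusted p of 0.00719, and adjusted p = 0.658 with an estimated correlation. Gstm3 (1.84, from 13.49 ± 0.46 to 15.33 ± 0.41), Gstm2 (1.10) and the quinone reductase gene Nqo1 (1.03) rose among NRF2 targets, which counted 6 higher, 0 lower and 28 neither of 34 (7 and 1 adjusted over the list alone). Their median was 0.28 with an adjusted p of 0.00159, and adjusted p = 0.318 with an estimated correlation. The microtubule regulator gene Stmn1 rose from 6.82 ± 0.35 to 8.96 ± 0.56 (2.14) and the replication helicase gene Mcm6 by 1.27. Cell cycle genes had 4 higher, 0 lower and 34 neither of 38 (5 higher adjusted over the list alone). The median of 0.41 had an adjusted p of 1.27e-06, and adjusted p = 0.618 with an estimated correlation. The survival gene Bcl2 (1.65), its relative Bcl2a1b (1.05) and the caspase genes Casp12 (1.57) and Casp1 (0.71) rose, with Bcl2a1b and Casp12 not above background in WT (at least 0.51 and 1.54). The cell death list counted 6 higher, 0 lower and 17 neither of 23 (10 higher adjusted over the list alone), with a median of 0.39 and an adjusted p of 8.06e-05, and adjusted p = 0.196 with an estimated correlation. Eng, the endoglin gene, rose from 10.75 ± 0.51 to 11.85 ± 0.41 (1.10). Sinusoidal endothelium had 2 higher, 0 lower and 19 neither of 21 (4 higher adjusted over the list alone). The median of 0.23 had an adjusted p of 0.00572, which became 0.270 without WT_8w replicate 1, and adjusted p = 0.627 with an estimated correlation. The p53 target Plk2 rose by 1.47, and p53 and DNA damage genes counted 2 higher, 0 lower and 31 neither of 33 (2 higher adjusted over the list alone). Their median of 0.17 had an adjusted p of 0.0376, lost without KO_8w replicate 5 (0.114), KO_8w replicate 3 (0.0546) or WT_8w replicate 2 (0.0558), with quantile normalization repeated (0.0748) or with the dimmest 25% of genes left out (0.0899), and adjusted p = 0.318 with an estimated correlation.

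Mitochondrial respiratory chain genes had 0 of 33 called singly at 8 weeks, genome-wide. The median of -0.22 had an adjusted p of 0.00572, and adjusted p = 0.720 with an estimated correlation, and 0.0701 with quantile normalization repeated. Cholesterol genes counted 0 higher, 1 lower and 18 neither of 19 (1 lower adjusted over the list alone), with a median of -0.29 and an adjusted p of 0.0211, and adjusted p = 0.733 with an estimated correlation. That call was lost without WT_8w replicate 2 (0.151) or KO_8w replicate 2 (0.0719), 3 (0.0658) or 5 (0.231), with quantile normalization repeated (0.0748) and with equal medians (0.0785). Unfolded protein response and ATF4 targets had 0 higher, 1 lower and 34 neither of 35 (0 adjusted over the list alone). The median of -0.14 had an adjusted p of 0.0382, and adjusted p = 0.627 with an estimated correlation. This call was lost without KO_8w replicate 3 (0.0656) or 5 (0.163) or WT_8w replicate 3 (0.243), with quantile normalization repeated (0.122), equal medians (0.0865), array weights (0.0563) and only the 2 groups in the fit (0.0546). The bile acid genes Baat (-0.83) and Cyp8b1 (-1.51) fell, and their list had 1 higher and 3 lower of 27 with an adjusted p of 0.0546. Lists of lipogenesis (median 0.17, adjusted p = 0.483), gluconeogenesis (-0.18, 0.659) and P450 enzymes (-0.19, 0.441) were not called at 8 weeks. Bhmt, which remethylates homocysteine, fell by 0.60 in the urea cycle and amino acid list (adjusted p = 0.166). Hepatocyte identity (-0.07, adjusted p = 0.140) was not called either. At 8 weeks 16 lists were called with the preset correlation. The 5 that held with an estimated correlation were ductular (adjusted p = 0.0238), stellate (0.0255), macrophage (0.00412), chemokine (0.0255) and female-biased (0.0255).

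**Figure D3:**
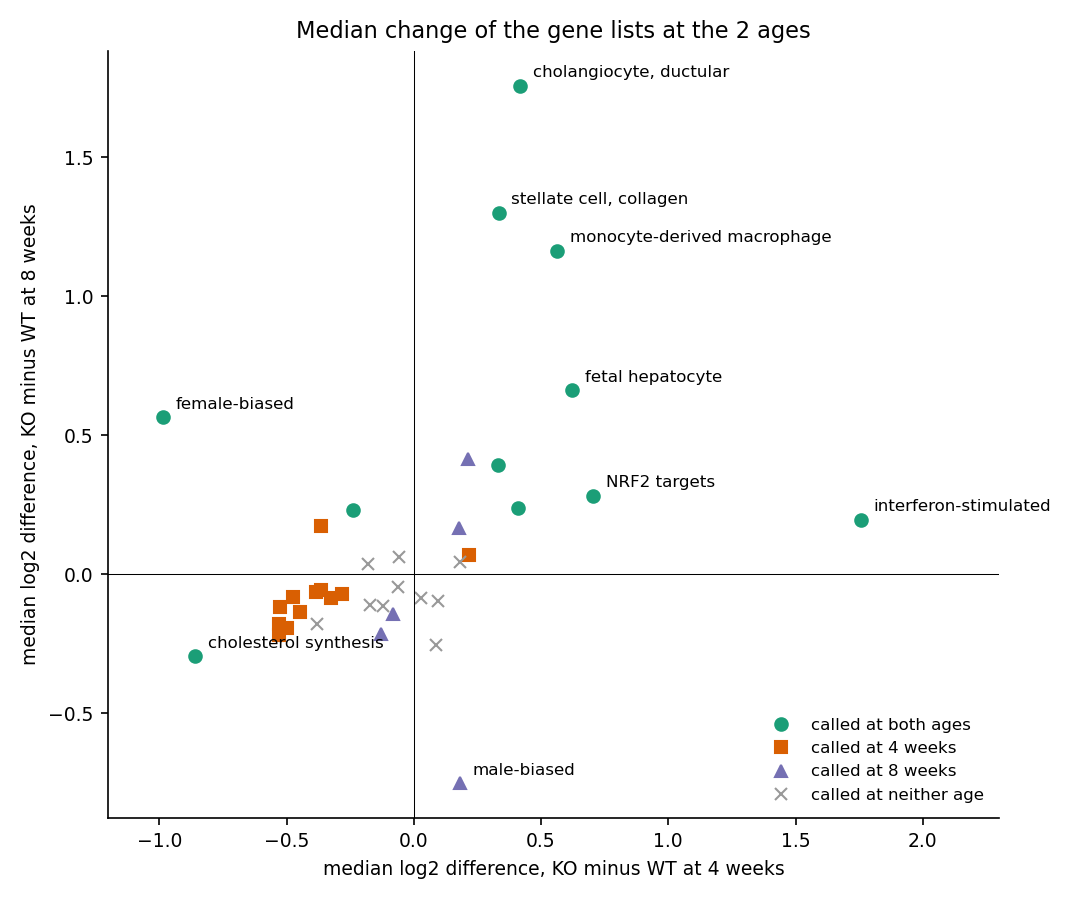
Median log2 difference KO minus WT of each of the 38 lists at 4 weeks (horizontal) and at 8 weeks (vertical), with 1 point per list and no error bars. Marker shape gives the age at which the list was called, and the interferon list lay at 1.76 and 0.20 and the ductular list at 0.42 and 1.76.

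The interaction test asked which KO effects differed between the ages. Among called genes Slc22a26 had the largest positive difference (6.51, SE 0.75, adjusted p = 6.72e-05), since its KO minus WT difference was -3.57 at 4 weeks and its KO mean lay above WT at 8 weeks (9.24 ± 1.46 against 6.30 ± 0.28). Hao2 (4.18), Pdzk1ip1 (4.16), Sparcl1 (4.11) and Fam180a (3.98) followed. The largest negative differences among called genes were those of Elovl3 (-6.85), Ifit1 (-4.26), the feature annotated to Mup20 (-4.19), Susd4 (-3.86) and Selenbp2 (-3.68). Hao2 was not above background in either group at 8 weeks (3.88 ± 0.27 and 4.18 ± 0.36), and Mup20 lay near the top of the scale in both (19.11 ± 0.13 and 19.18 ± 0.11). A KO effect could hardly show there, so these 2 values largely restate the 4-week difference. Of all 595 called genes 25 were not above background in either group at 8 weeks, and 43 in either group at 4 weeks. In all, 399 genes had a higher and 196 a lower KO effect at 8 weeks than at 4 weeks (3.05% of those tested), of which 308 and 119 by at least 2-fold. The 399 became 247 without KO_8w replicate 1 and 251 without KO_4w replicate 2.

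In this and the next paragraph a shift is one of the KO effect, not of expression with age. Female-biased genes shifted upward, with 15 higher, 0 lower and 16 neither of 31 (18 higher adjusted over the list alone), a median of 2.21 and an adjusted p of 1.72e-19. Cyp2c69 (3.19) was 1 of them. The mean of this list fell with age in both genotypes, from 11.82 to 7.54 in WT and from 10.63 to 8.48 in KO. Its members Hao2, Sult3a1 and Sult2a2 (4.56 in WT and 4.74 in KO) were not above background in either group at 8 weeks. For them the shift largely restates the 4-week difference, and the list median rests in part on such members. Male-biased genes shifted downward, with 8 lower and 18 neither of 26 (1 higher and 13 lower adjusted over the list alone), and a median of -0.93. Their adjusted p was 3.03e-10, and adjusted p = 0.204 with an estimated correlation. Of the male-biased members, Mup20 lay near the top of the scale at 8 weeks (19.11 in WT and 19.18 in KO). Susd4 was close to background at 4 weeks (5.95 and 5.96), where a fall of its 8-week size could not show. Interferon genes shifted downward with Ifit1, Rsad2 (-3.51) and Cxcl10 (-3.33), and 12 were lower, 0 higher and 16 neither of 28 (22 lower adjusted over the list alone). The median was -1.29 and the adjusted p 3.19e-21. NRF2 targets Gsta2 (-2.90) and Srxn1 (-3.01) had a smaller KO effect at 8 weeks, and their list counted 8 lower, 0 higher and 26 neither of 34 (2 higher and 13 lower adjusted over the list alone). The median of -0.40 had an adjusted p of 1.18e-06, and adjusted p = 0.126 with an estimated correlation. Pkhd1 (3.93, at least 3.87 above background), Prom1 (3.69) and Bicc1 (2.73) had a larger KO effect at 8 weeks. The ductular list counted 7 higher, 1 lower and 14 neither of 22 (12 and 2 adjusted over the list alone). Its median of 1.02 had an adjusted p of 3.27e-09, and adjusted p = 0.204 with an estimated correlation. Pdgfrb (2.82, adjusted p = 5.41e-05) and Mmp2 (3.52) shifted upward in the stellate list. Mmp13 shifted downward (-2.84, or -2.83 with the background level in place of both WT means, which were not above it). That list had 8 higher, 1 lower and 28 neither of 37 (21 and 1 adjusted over the list alone). The median of 1.06 had an adjusted p of 1.27e-13, and adjusted p = 0.204 with an estimated correlation. Stab2 (1.26) shifted upward in the endothelial list, which counted 3 higher of 21, with a median of 0.70 and an adjusted p of 1.81e-06, and adjusted p = 0.263 with an estimated correlation.

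Stard4 (1.27) shifted upward in the cholesterol list, with a median of 0.60 and an adjusted p of 9.51e-05, and adjusted p = 0.449 with an estimated correlation. Fads1 (0.99) did so in the lipogenesis list, with a median of 0.53 and an adjusted p of 0.00538, and adjusted p = 0.449 with an estimated correlation. Kyat1 (1.67) did so in the urea cycle and amino acid list, with a median of 0.34 and an adjusted p of 0.00139, and adjusted p = 0.476 with an estimated correlation. F11 (1.20) and Itih1 (1.04) shifted upward in the hepatocyte identity list, whose median was 0.17 with an adjusted p of 0.00973, and adjusted p = 0.364 with an estimated correlation. The IGF-binding protein gene Igfbp3 (2.36) shifted upward in the growth hormone list, with a median of 0.37 and an adjusted p of 0.0109, and adjusted p = 0.115 with an estimated correlation. Lyz2 (2.10) and the lipoprotein lipase gene Lpl (2.38), which is also on the female-biased list, shifted upward in the macrophage list. The list median was 0.25 with an adjusted p of 0.0129, and adjusted p = 0.449 with an estimated correlation. That call was lost without KO_4w replicate 1 (0.0636). Kupffer cell markers had 0 of 16 called singly, with a median of -0.58 and an adjusted p of 0.00605, and adjusted p = 0.204 with an estimated correlation. The cell cycle median of 0.28 had an adjusted p of 0.0149, and adjusted p = 0.688 with an estimated correlation. Leaving out any of 5 arrays ended that call, namely WT_4w replicate 3 (0.363) or 4 (0.114), KO_4w replicate 3 (0.0873) or 5 (0.0810), or KO_8w replicate 5 (0.0767), as did array weights (0.0548) and the fit without the 3 arrays with muscle transcripts (0.514). The unfolded protein response median of -0.16 had an adjusted p of 0.0332, and adjusted p = 0.476 with an estimated correlation. It was lost without WT_4w replicate 2 (0.0722) or 5 (0.113), KO_4w replicate 4 (0.0649) or 5 (0.0771), WT_8w replicate 3 (0.126) or KO_8w replicate 5 (0.122), with array weights (0.0577) and without the 3 arrays with muscle transcripts (0.178). Of the 16 lists called, the interferon (adjusted p = 0.0490) and female-biased (adjusted p = 0.00105) lists held with an estimated correlation.

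**Figure D4:**
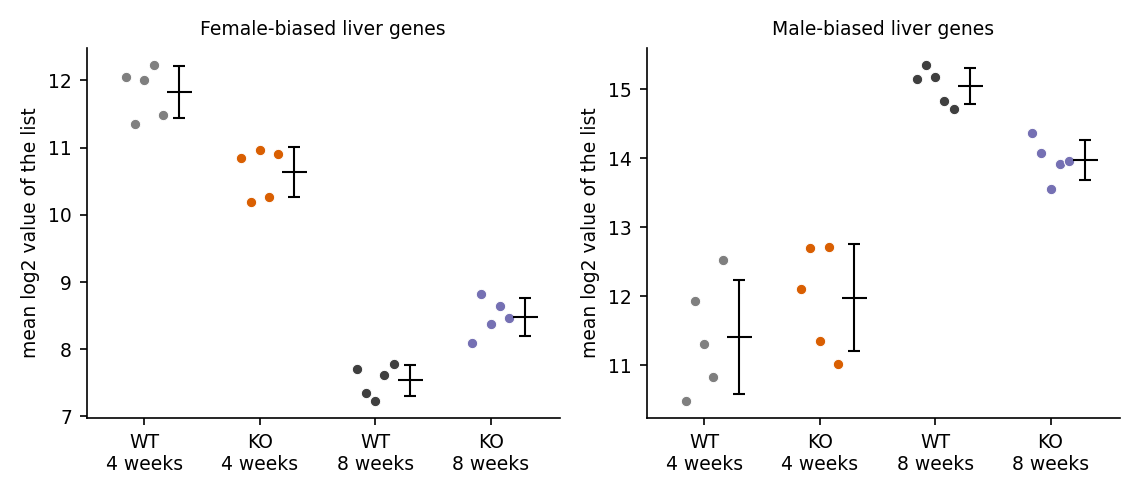
Mean log2 signal of the female-biased and the male-biased list in each array by group, with points for arrays and bars for mean ± SD (n = 5). The female-biased mean was 11.82 and 10.63 in WT and KO at 4 weeks and 7.54 and 8.48 at 8 weeks, and the male-biased mean was 11.41 and 11.98, then 15.05 and 13.98.

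KO effects at the 2 ages were compared across the 19505 genes, with a Pearson correlation of 0.343 (jackknife SE 0.0684) and a Spearman correlation of 0.302. Genes higher at both ages numbered 200, against 45.3 if the calls were independent, and genes lower at both 96, against 17.6. Only 4 genes were higher at 4 and lower at 8 weeks (15.1 if independent), and 11 the reverse (52.7).

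Age changed expression in WT liver. Elovl3 rose from 5.47 ± 1.90 at 4 weeks to 16.77 ± 1.05 at 8 weeks (11.30, adjusted p = 2.93e-09) and Cyp7b1 from 9.35 ± 0.70 to 16.84 ± 0.62 (7.49, adjusted p = 1.68e-11), both with male-biased expression. The complement gene C6 rose by 7.92, and the near-identical paralogs Cyp4a12a (11.13) and Cyp4a12b (8.75) could not be told apart with certainty. Hao2 fell from 12.67 ± 0.53 to 3.88 ± 0.27 (-8.79, adjusted p = 3.73e-13) and Slc22a27 from 12.70 ± 0.54 to 4.29 ± 0.43 (-8.41). The aldo-keto reductase gene Akr1c18 (-8.37) and the features of the paralogs Sult2a2 (-10.45) and Sult2a1 (-8.49) fell too. At 8 weeks Hao2, Slc22a27, Akr1c18 and Sult2a2 were not above background, so these falls were at least 7.48, 7.50, 8.25 and 9.82. In all, 723 genes were higher and 1021 lower at 8 weeks (8.94% of those tested), of which 214 and 508 by at least 2-fold. The 723 became 472 without WT_4w replicate 4, which held muscle transcripts. The groups did not overlap for 1772 genes (9.08%), against 0.794% by chance. With array medians set equal 971 were higher and 898 lower, so the share of higher genes was 52.0% in place of 41.5%.

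Cell cycle genes fell with age in WT, with Mcm6 from 10.70 ± 0.74 to 6.66 ± 0.53 (-4.04) and the mitotic gene Ube2c from 8.40 ± 1.06 to 3.97 ± 0.24 (-4.43, at least 3.20 above background). Of 38 genes 36 were lower, 0 higher and 2 neither (38 lower adjusted over the list alone), with a median of -2.11 and an adjusted p of 1.93e-52. Female-biased genes had 28 lower, 0 higher and 3 neither of 31 (28 lower adjusted over the list alone), with a median of -3.60 and an adjusted p of 8.98e-51. Male-biased genes had 21 higher, 0 lower and 5 neither of 26 (23 higher adjusted over the list alone), with a median of 2.99 and an adjusted p of 1.31e-34. The matrix genes Sparc (-4.06) and Col3a1 (-3.38) fell, and the stellate list counted 13 lower of 37 (22 adjusted over the list alone). Its median of -0.74 had an adjusted p of 6.64e-13, and adjusted p = 0.183 with an estimated correlation. The sterol genes Idi1 (-1.66) and Hmgcs1 (-1.81) fell, and 12 of 19 cholesterol genes were lower (13 adjusted over the list alone). The median of -1.04 had an adjusted p of 1.20e-10, and adjusted p = 0.172 with an estimated correlation. Lyve1 (-2.47) and Cdh5 (-1.42) fell among endothelial genes, of which 8 of 21 were lower, with a median of -0.56 and an adjusted p of 9.84e-09, and adjusted p = 0.172 with an estimated correlation. The PPARalpha target Cyp4a14 fell from 17.21 ± 0.30 to 9.10 ± 1.20 (-8.11), and is also on the female-biased list. Of 27 fatty acid oxidation genes 9 were lower. Their median of -0.44 had an adjusted p of 3.15e-07, and adjusted p = 0.172 with an estimated correlation. The imprinted gene Mest (-3.74) and the oncofetal genes Gpc3 (-3.30, at least 2.48 above background) and Igf2bp3 (-2.21) fell, and 5 of 20 fetal genes were lower, with a median of -0.57 and an adjusted p of 3.15e-07, and adjusted p = 0.102 with an estimated correlation.

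The coactivator gene Ppargc1a (-2.63) and Sdhd (-0.54) fell with age in WT, and 5 of 33 mitochondrial genes were lower. The median was -0.30 with an adjusted p of 3.61e-06, and adjusted p = 0.387 with an estimated correlation. In WT_4w replicate 4, which held muscle transcripts, the list mean was 13.59 against 13.21 in the next array, and without it the median was -0.21 and the list was still called. Acaca (-1.83) and Fads2 (-1.11) fell, and 7 of 19 lipogenic genes were lower, with a median of -0.45 and an adjusted p of 6.15e-06, and adjusted p = 0.211 with an estimated correlation. Usp18 (-2.14) and Xaf1 (-1.75) fell among interferon genes, of which 5 of 28 were lower. The median of -0.43 had an adjusted p of 2.34e-05, and adjusted p = 0.385 with an estimated correlation. Lpl (-4.55), which is also on the female-biased list, fell in the macrophage list (2 higher and 5 lower of 25). The list median of -0.16 had an adjusted p of 0.0276, and adjusted p = 0.466 with an estimated correlation. Leaving out WT_4w replicate 1 (0.0790), WT_4w replicate 4 (0.0624) or WT_8w replicate 3 (0.0732) ended this call, as did the dimmest 25% of genes left out (0.0846), the fit without the 3 arrays with muscle transcripts (0.0636) and ranks (0.0996). Vcam1 (-2.32) and Ccl9 (-1.45) fell in the chemokine list (2 higher and 5 lower of 34), whose median of -0.05 had an adjusted p of 0.0303, and adjusted p = 0.323 with an estimated correlation. That call ended without WT_4w replicate 1 (0.111) or WT_8w replicate 3 (0.0770), and with ranks (0.106). Of 13 lists called, the cell cycle (adjusted p = 0.0115), female-biased (2.39e-06) and male-biased (0.00624) lists held with an estimated correlation.

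In KO liver Nox4, an NADPH oxidase gene, rose from 4.40 ± 0.33 at 4 weeks to 9.72 ± 0.65 at 8 weeks (5.32, at least 4.68 above background, adjusted p = 1.07e-11), and Hsd3b5, a male-biased steroid dehydrogenase gene, rose by 6.24. C6 (5.54) rose, as did the paralogs Cyp4a12a (6.08) and Cyp4a12b (5.93). Mir675, whose feature may read its host transcript H19, fell from 15.36 ± 1.92 to 6.01 ± 1.24 (-9.35). Akr1c18 (-7.54), Rgs16 (-6.38) and the features of Sult2a2 (-8.24, at least 7.96 above background) and Sult2a1 (-6.87) fell too. All of these genes moved in the same direction in WT. There Nox4 rose from 4.83 ± 0.25, not above background, to 11.11 ± 0.30, and Hsd3b5 from 10.13 ± 2.73 to 16.41 ± 0.29. Mir675 went from 10.82 ± 3.78 to 5.15 ± 0.26 in WT, and Rgs16 from 13.07 ± 1.49 to 6.60 ± 1.67. The 2 KO groups also differed in Ogt signal, which was 8.14 ± 0.53 at 4 weeks and 9.81 ± 0.21 at 8 weeks. Age and Ogt signal could not be separated in this comparison. In all, 1532 genes were higher and 1323 lower (14.6% of those tested), of which 499 and 511 by at least 2-fold. The groups did not overlap for 1848 genes (9.47%), against 0.794% by chance.

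Interferon genes fell with age in KO, with Rsad2 from 12.13 ± 0.94 to 7.64 ± 0.77 (-4.49) and Usp18 from 12.06 ± 0.38 to 8.05 ± 0.41 (-4.01). Of 28 genes 24 were lower, 0 higher and 4 neither (26 lower adjusted over the list alone), with a median of -1.99 and an adjusted p of 4.99e-31. Cell cycle genes fell with Mcm6 (-3.57) and Pcna (-1.74), and 35 were lower, 0 higher and 3 neither of 38 (1 higher and 36 lower adjusted over the list alone), with a median of -1.69 and an adjusted p of 9.67e-35. NRF2 targets fell with Gstm3 (-2.50) and the pentose phosphate gene Pgd (-2.11), and counted 1 higher, 17 lower and 16 neither of 34 (1 and 21 adjusted over the list alone), with a median of -0.46 and an adjusted p of 3.78e-09. Slc22a27 fell by 4.99 and Hao2 by 4.61 (at least 3.77 above background), and 18 of 31 female-biased genes were lower (21 adjusted over the list alone), with a median of -1.55 and an adjusted p of 2.55e-15. Cyp7b1 rose by 4.44, and 16 of 26 male-biased genes were higher (18 adjusted over the list alone), with a median of 1.42. Their adjusted p was 4.43e-12, and adjusted p = 0.114 with an estimated correlation. Pkhd1 (3.29) and Bicc1 (2.29) rose and Krt18 (-1.54) fell in the ductular list (13 higher and 3 lower of 22). The median of 0.88 had an adjusted p of 1.81e-05, and adjusted p = 0.340 with an estimated correlation. The Kupffer cell genes Clec4f (-2.16) and Cd5l (-1.93) fell, and their list counted 1 higher and 8 lower of 16, with a median of -0.85 (adjusted p = 1.57e-04, and adjusted p = 0.0664 with an estimated correlation). The stellate list was not called (9 higher and 5 lower of 37, median 0.28, adjusted p = 0.193), but it was without the 3 arrays with muscle transcripts (adjusted p = 0.00395).

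The cytochrome c gene Cycs (-1.04) and Ndufs1 (-1.05) fell with age in KO, and 13 of 33 mitochondrial genes were lower. The median was -0.35 with an adjusted p of 2.01e-06, and adjusted p = 0.340 with an estimated correlation. Afp (-2.44) and Igf2bp3 (-1.77) fell in the fetal list (2 higher and 5 lower of 20), with a median of -0.44 and an adjusted p of 0.00108, and adjusted p = 0.328 with an estimated correlation. Cyp4a14 (-4.81), which is also on the female-biased list, and Hadhb (-0.89) fell in the fatty acid oxidation list (7 lower of 27). The list median was -0.33 with an adjusted p of 0.00142. The call was lost without the 3 arrays with muscle transcripts (0.0541), and adjusted p = 0.340 with an estimated correlation. Kyat1 (1.31) and Oat (1.09) rose in the urea cycle list (9 higher of 25), with a median of 0.50 and an adjusted p of 0.00142, which became 0.0540 without KO_8w replicate 3, and adjusted p = 0.494 with an estimated correlation. The complement gene C9 (1.99) and F11 (0.92) rose in the hepatocyte identity list (9 higher of 33), with a median of 0.12 and an adjusted p of 0.00965, and adjusted p = 0.330 with an estimated correlation and 0.1595 with quantile normalization repeated. Cxcl10 (-4.38) and Cxcl9 (-3.68) fell in the chemokine list (2 higher and 7 lower of 34), with a median of -0.20 and an adjusted p of 0.0134, and adjusted p = 0.328 with an estimated correlation. Tsc22d3, a glucocorticoid target, rose by 2.53 and Hlf by 1.04 in the clock list (2 higher of 20), with a median of 0.59 and an adjusted p of 0.0342, and adjusted p = 0.330 with an estimated correlation. Mlkl (-1.84) and Tnfrsf12a (-2.01) fell in the cell death list (1 higher and 4 lower of 23), with a median of -0.14 and an adjusted p of 0.0366, and adjusted p = 0.494 with an estimated correlation. Cyp27a1 (1.42) and Lgr5 (1.03) rose in the pericentral list (8 higher and 2 lower of 23), with a median of 0.34 and an adjusted p of 0.0419, and adjusted p = 0.394 with an estimated correlation. The clock call ended without KO_4w replicate 1 (0.0558), KO_4w replicate 2 (0.0519) or KO_8w replicate 5 (0.132), and with the dimmest 25% of genes left out (0.0653). The cell death call ended without KO_4w replicate 3 (0.0541), KO_4w replicate 5 (0.0894), KO_8w replicate 3 (0.151) or KO_8w replicate 4 (0.130), with array weights (0.0519), with the dimmest 25% of genes left out (0.0653) and without the 3 arrays with muscle transcripts (0.156). The pericentral call ended without KO_4w replicate 3 (0.0980), KO_4w replicate 5 (0.1002), KO_8w replicate 1 (0.0527), KO_8w replicate 2 (0.108) or KO_8w replicate 4 (0.0925), with quantile normalization repeated (0.0627), equal medians (0.0514) or the dimmest 25% left out (0.0774), and without the 3 arrays with muscle transcripts (0.0638). Of 16 lists called, interferon (adjusted p = 0.0106), cell cycle (0.0431), female-biased (0.00415) and NRF2 (0.0431) held with an estimated correlation.

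Changes with age were correlated between WT and KO (Pearson 0.604, Spearman 0.349). Genes higher with age in both genotypes numbered 327, against 56.8 if independent, and genes lower in both 472, against 69.3. Opposite calls were made for 5 and 17 genes, against 49.0 and 80.2 if independent.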

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

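The tests of an effect of the knockout on muscle transcripts, of mislabelled arrays, of non-hepatocyte cells, of hepatocytes with intact Ogt, of female animals and of a slower fall in KO were chosen only after the results were seen.

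Skeletal muscle transcripts were high in WT_4w replicate 4, KO_4w replicate 4 and KO_4w replicate 5. Of 33 muscle genes that had not been used to find these arrays 78.8% (26) were higher in all 3 arrays than in the other 7 at 4 weeks, against 0.833% by chance. A bound of 80% had been set before this test, so muscle tissue in the sample was left undecided by it. An effect of the knockout is argued against, since the WT array lay above the lower of the KO arrays in the mean of the 33 genes by 0.97. Tissue taken with the liver remains likely but open, because how the livers were dissected was not given in the sources used here.

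Ogt was close to the WT level in the arrays labelled KO at 8 weeks. Swapped labels are argued against, since 0 of 5 arrays labelled KO lay at or below the highest WT array in the mean of the 312 genes called at least 2-fold higher at 4 weeks (8.25 to 8.71 against 7.67 to 7.75). Hepatocytes with intact Ogt cannot be told apart, since genes lower by at least 2-fold in 3 arrays per 4-week group had at 8 weeks a median share of 0.330 (0.212 to 0.531 over 100 choices of arrays) of their difference in the 4-week arrays left out, and higher genes 0.407 (0.270 to 0.7102), where a bound of 0.5 in every choice was asked for. More cells other than hepatocytes cannot be told apart either, since hepatocyte identity genes had a median difference of -0.072 at 8 weeks and the Ogt level of the other cells is not known here. What the feature reads in a deleted allele stays open as well.

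Female-biased genes were lower in KO at 4 weeks and higher in the arrays labelled KO at 8 weeks. Female animals are argued against by Eif2s3y, which varied by 1.01 over all 20 arrays, and muscle transcripts by the interaction median of 2.03 without the 3 arrays (2.21 with them). A slower fall toward the 8-week state in KO would by itself leave these genes higher in KO at 4 weeks. The list median there was -0.98, in the direction of the 8-week state. That value is part of the flagged pattern, so it is not a separate test of this explanation. For the 8-week part a slower fall cannot be told apart, since cell cycle genes, which fall with age in WT, had a median of 0.41 whose call was lost with an estimated correlation. A change in growth hormone signalling and the course of these genes before 4 weeks stay open, because hormone levels and younger livers were not analysed here.

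Other ways to split the arrays gave fewer calls than the real groups. In each of the 5 comparisons 1 of 100 splits, the real one, reached the real number of calls. The highest count of any other split was 119 for KO against WT at 4 weeks (1985 in the real groups) and 422 at 8 weeks (1284). It was 445 for the interaction (595), 84 for age in WT (1744) and 613 for age in KO (2855). For the interaction the genotype labels were shuffled within each age. That stands for no KO effect at either age, not for equal effects, so it does not test whether the effects differ. In every comparison the other splits carry the real group differences as spread within groups, which lowers their counts.

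The KO effect differed between the ages for 595 genes and for Ogt (1.16), whose call was lost on leaving out any of 7 arrays (adjusted p 0.0514 to 0.0605). Of the 595, 399 had a higher effect at 8 weeks, a count that fell to 247 without KO_8w replicate 1 and to 251 without KO_4w replicate 2. Of 31 genes named at either age 22 had a called difference, and the other 9 did not. These genes were chosen for a large KO effect at 1 age, which is a part of the difference tested. A share above the 3.05% of all genes was therefore favoured by the choice. Among genes named at 4 weeks the differences were Elovl3 -6.85, Mup20 -4.19, Gsta2 -2.90, Ifit1 -4.26, Irf7 -3.44, Mmp13 -2.84 (-2.83 with the background level in place of both WT means) and Ifit3b -3.30. They were positive for Hao2 (4.18), Slc22a26 (6.51), Hsd3b1 (2.85), Sult3a1 (3.21), Cyp2c69 (3.19) and Ces1f (2.11). At 8 weeks Mup20 lay near the top of the scale in both groups (19.11 and 19.18), Hao2 (3.88 and 4.18) and Sult3a1 (4.57 and 4.75) were not above background in either, and Hsd3b1 was close to it (5.60 and 5.19), so these 4 differences largely restate those at 4 weeks. Among genes named at 8 weeks they were Sparcl1 4.11, Pdzk1ip1 4.16, Ntrk2 2.44, Fam180a 3.98, Epcam 3.62 (at least 3.44 above background), Lum 3.16, Susd4 -3.86, Cyp7b1 -3.05 and Selenbp2 -3.68. List medians of the interaction were positive for female-biased genes (2.21), stellate (1.06), ductular (1.02), endothelial (0.70), cholesterol (0.60), lipogenesis (0.53), growth hormone (0.37), urea cycle (0.34), cell cycle (0.28), macrophage (0.25) and hepatocyte identity genes (0.17). They were negative for interferon (-1.29), male-biased (-0.93), Kupffer (-0.58), NRF2 (-0.40) and unfolded protein response genes (-0.16). Of these 16 lists only female-biased (adjusted p = 0.00105) and interferon genes (0.0490) held with an estimated correlation.

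Single arrays stood apart from the other 4 of their group in 20 of 224 sets of values, where 11.2 would arise by chance. In WT at 4 weeks replicate 1 had list means of 11.67 for fatty acid oxidation, 14.82 for acute phase proteins and 7.90 for interferon genes. Replicate 4 of that group had 7.03 for the held-out muscle genes and 13.59 for mitochondrial genes. In KO at 4 weeks replicate 4 had 8.71 for hexosamine genes, 8.01 for p53 genes and 9.61 for Ifit1, replicate 5 had 4.79 for neutrophil markers and 12.64 for iron genes, and replicate 2 had 5.72 for Sult3a1. In WT at 8 weeks replicate 1 had 6.17 for fetal, 7.85 for endothelial, 15.38 for acute phase, 11.51 for NRF2 and 8.99 for clock genes, and replicate 3 had 10.67 for the unfolded protein response. Among arrays labelled KO at 8 weeks replicate 3 had 15.53 for periportal, replicate 5 9.05 for clock and replicate 2 10.64 for lysosome genes.

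Features without a gene symbol were not named here, and 201 of 2634 were called at 4 weeks and 130 at 8 weeks.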

How the results depend on the processing

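The fit without the 3 arrays with muscle transcripts was the only alternative chosen after the results were seen. Array medians set equal gave 856 lower genes at 8 weeks (321 as deposited) and 98 lower by at least 2-fold (53), and the median of all genes moved by -0.114 at 8 weeks. The shift is set by the construction of that scaling. With quantile normalization repeated 974 genes were higher and 1021 lower at 4 weeks, and 927 and 451 at 8 weeks. Leaving out single arrays gave 199 to 332 lower genes at 8 weeks, below the main count by over 1.5 times without KO_8w replicate 5 (199), WT_8w replicate 3 (203) and KO_8w replicate 2 (207). Higher genes of the interaction numbered 247 to 528, with 247 without KO_8w replicate 1 and 251 without KO_4w replicate 2 against 399. Higher genes with age in WT numbered 472 to 733, with 472 without WT_4w replicate 4 against 723, and the cause of these moves was not tested. The Ogt difference ran from -1.60 to -1.24 at 4 weeks and from -0.33 to -0.20 at 8 weeks. The Ogt interaction was lost without WT_4w replicate 2 (0.0592), 3 (0.0605) or 4 (0.0514), WT_8w replicate 1 (0.0585) or 3 (0.0573), or KO_8w replicate 1 (0.0552) or 2 (0.0582). The correlation of KO effects between the ages ran from 0.303 to 0.366. No call reversed its direction under any alternative.

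Of 500 calls of named genes 67 were lost on leaving out at least 1 array, and of 84 list calls 16. Quantile normalization lost 19 gene and 7 list calls, equal medians 12 and 3, and only the 2 compared groups in the fit 33 of 435 and 1 of 68. The variance trend lost 10 and 0, array weights 4 and 4, all features tested 4 and 0, the mean of features 1 and 0, and the filter on dim genes 0 of 495 and 6. An estimated correlation lost 63 of 84 list calls, and ranks lost 2 and gained 6. With the replicate block 818 genes were higher and 986 lower at 4 weeks, 912 and 258 at 8 weeks, and 328 and 160 in the interaction. Deviations of same-numbered arrays correlated above 0.1 in 4 of 5 pairs of WT and KO at 4 weeks (0.139, 0.320, 0.159 and 0.479 for replicates 1 to 4, and -0.146 for replicate 5), in 1 of 5 at 8 weeks and in 0 of 20 pairs across ages. Both arrays of replicate 4 held muscle transcripts, and of replicate 5 only KO did. With the 3 such arrays left out the correlations were 0.0130, 0.128 and 0.00922 for replicates 1 to 3, so the numbers were not taken to pair the arrays. The block lost 15 gene calls and 0 list calls and gained 3 lists, namely gluconeogenesis in the interaction (adjusted p = 0.0331), Kupffer markers with age in WT (0.0476) and cholesterol with age in KO (0.0418). Without the 3 arrays with muscle transcripts 305 genes were higher and 442 lower by at least 2-fold at 4 weeks (312 and 319 with all arrays). All calls were 370 and 147 in the interaction, 488 and 859 with age in WT and 1363 and 1154 with age in KO. Of the calls made with all arrays 1346 of 1985 at 4 weeks and 400 of 595 in the interaction were kept, and the cause was not tested. Ogt was -1.62 at 4 weeks in that fit, and 7 of 68 list calls were lost and 5 gained.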

Other observations

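No test was chosen after the results were seen for the values in this part, except that the genes of the last paragraph were chosen after their values were seen.

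Oga, which encodes the enzyme that removes O-GlcNAc, fell at 4 weeks from 11.47 ± 0.20 in WT to 9.98 ± 0.50 in KO (-1.49, adjusted p = 1.79e-04, n = 5 each). Uap1l1, a homolog of the enzyme that makes UDP-N-acetylglucosamine, rose from 5.43 ± 0.33 to 7.01 ± 0.46 (1.58). The hexosamine list had 1 higher, 2 lower and 10 neither of 13 at 4 weeks, with a median of -0.12 and an adjusted p of 0.190. At 8 weeks Gfpt2, which encodes the first enzyme of the hexosamine pathway, rose by 1.13 (5.27 ± 0.57 to 6.40 ± 0.50), and Oga was not among the called genes. The list median was then -0.11 and the mean 0.05, so their signs differed, with an adjusted p of 0.978. The glucose-responsive genes Pklr (-2.52), Arrdc4 (-1.21) and Mlxipl, which encodes the carbohydrate sensor ChREBP (-1.02), fell at 4 weeks. Glycolysis and ChREBP targets counted 2 higher, 4 lower and 11 neither of 17, with a median of -0.38 (adjusted p = 0.179), and 0 of 17 called at 8 weeks (median -0.18, adjusted p = 0.520).

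Stress genes moved singly at 4 weeks. Ddit3, which encodes CHOP, rose from 7.33 ± 0.30 to 9.12 ± 0.71 (1.79, adjusted p = 7.75e-04) and Atf3 by 1.11. The unfolded protein response list had 6 higher and 2 lower of 35, and its median of -0.08 lay opposite to its mean of 0.08 and to the direction of the test (adjusted p = 0.747). Mdm2, the p53 target that degrades p53, rose by 0.88 and the reductase gene Dcxr fell by 1.18. The p53 list counted 4 higher and 1 lower of 33 (median 0.18, adjusted p = 0.0904). Saa3, an acute phase gene, rose by 2.46, while Orm1 fell by 2.84 and Crp by 0.65. Acute phase proteins had a median of -0.17 and a mean of 0.05, of opposite sign, with an adjusted p of 0.726 at 4 weeks and 0.314 at 8 weeks (median -0.11). The autophagy receptor gene Sqstm1 (1.12) and the lysosomal enzyme gene Hexa (0.83) rose and Bnip3 fell by 1.24. The lysosome list had a median of 0.10 and a mean of -0.01, of opposite sign (adjusted p = 0.485). At 8 weeks Hexa (1.27) and the sterol carrier gene Npc2 (0.75) rose in that list, whose adjusted p was 0.852. Tfr2, an iron sensor gene, fell by 0.89 and the ferritin gene Fth1 rose by 0.44 at 4 weeks, with 3 higher and 1 lower of 19 iron genes (median 0.18, adjusted p = 0.385). The iron list had an adjusted p of 0.607 at 8 weeks.

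The complex I gene Ndufs8 fell by 0.86 at 4 weeks, and the mitochondrial list had 0 higher and 2 lower of 33 (median -0.13, adjusted p = 0.0952). Tsc22d3 fell from 12.14 ± 0.47 to 10.46 ± 0.47 (-1.68), and clock genes counted 0 higher and 1 lower of 20 (median -0.18, adjusted p = 0.254), with an adjusted p of 0.852 at 8 weeks. Cell cycle genes had 1 higher and 1 lower of 38 at 4 weeks, with a median of 0.21 and an adjusted p of 0.126. Cd5l, a Kupffer cell gene, rose by 1.14 at 4 weeks, where the Kupffer list had 3 higher and 0 lower of 16 (median 0.09, adjusted p = 0.190). At 8 weeks the haemoglobin scavenger gene Cd163 fell by 1.69 and Fcna by 0.96, and the Kupffer list had 0 higher and 2 lower (adjusted p = 0.0825). The T cell gene Cd4 fell by 0.79 at 8 weeks in the T and NK list (adjusted p = 0.678). Neutrophil markers had a median of -0.06 at 4 weeks (adjusted p = 0.747) and 0.06 at 8 weeks (adjusted p = 0.722). B and plasma cell markers had a median of -0.06 at 4 weeks (adjusted p = 0.390), and at 8 weeks a median of -0.05 and a mean of 0.04 of opposite sign (adjusted p = 0.920). Erythroid markers had a median of 0.03 and a mean of -0.01 at 4 weeks, of opposite sign (adjusted p = 0.858), and Car2 rose by 1.75 at 8 weeks in a list with an adjusted p of 0.920. Sult5a1 (-1.90 at 8 weeks, called but not above background in either group) is in the periportal list (adjusted p = 0.441), and the pericentral list had 1 higher and 1 lower (adjusted p = 0.920). Igfbp3 rose from 7.16 ± 0.76 to 8.88 ± 0.66 at 8 weeks (1.72). The growth hormone list had a median of -0.06 and a mean of 0.07 there, of opposite sign (adjusted p = 0.920). Fatty acid oxidation genes at 8 weeks had a median of -0.06 and a mean of 0.06, of opposite sign (adjusted p = 0.781), and the Y chromosome genes a median of -0.13 (adjusted p = 0.869).

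Lcn2 and Mt2, chosen after their values were seen, were highest in single arrays within groups, and the other arrays differed between groups as well. Lcn2, an acute phase gene, was 15.72 in WT_8w replicate 1 and 7.14 to 9.02 in the other WT arrays at 8 weeks. It was 14.37 in KO_8w replicate 5 and 10.85 to 11.43 in the other arrays labelled KO at 8 weeks. At 4 weeks it was 15.12 in WT_4w replicate 1, 9.65 to 11.57 in the other WT arrays and 13.03 to 14.22 in KO. The metallothionein gene Mt2 was 17.65 in WT_8w replicate 1 and 7.33 to 9.49 in the other WT arrays at 8 weeks. It was 18.50 in KO_8w replicate 5 and 12.41 to 14.71 in the other arrays labelled KO at 8 weeks. At 4 weeks Mt2 ran from 15.19 to 18.92 over the arrays of both genotypes.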
